A study of Homo sapiens with 4 samples.

How the data were processed

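Polyadenylation selection, library kit, strand and counting options are not given in the sources used here. Total RNA was extracted from PC-3M-luc cells 72 h after transfection with control or LSD1 duplexes, and each of the 4 libraries has its own table. The deposited values are raw read counts per RefSeq transcript, with no normalization, judged from the values since the tables have no header: all are whole numbers, and totals over all rows differ between libraries. TopHat2, HOMER, edgeR and DESeq 1.8.3, and the hg19 genome build, are named per the submitters' processing notes, with no role stated. The series design text calls the cells knockouts, whereas the sample labels describe RNAi, and the samples are treated here as knockdowns.

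Each table held 38767 rows, of which 965 carry a suffix for a further copy of a transcript in the genome. Gene symbols were found for 37205 rows in a RefSeq gene table and for 472 more in GENCODE metadata, which gave 22841 symbols, while 1090 rows matched none. Those unmatched rows held 1.38% to 1.40% of the counts and were left out of library sizes and tests. Because isoforms of a gene count the same reads again, the row with the highest mean over the 4 libraries stood for each of the 7517 symbols with several rows. Totals over all rows were 23730737 and 23565034 in control libraries and 22855909 and 24348184 in knockdown libraries. The 10 most abundant genes took 3.72% to 4.15% of the gene counts. Floors of 3 counts cover counting error only. No coordinates are given, since the reference used here for names and overlaps is of another build than hg19.

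Counts were normalized by TMM and filtered with filterByExpr (a count of 10, a total of 15). Genes were tested by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment over 13247 genes at a threshold of 0.05. The common dispersion was 0.00355, a biological coefficient of variation of 5.96%. CPM values are given as mean ± SD over 2 libraries. With 2 libraries per group, the p-values rest on a spread shared across genes.

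A set of 38 gene lists, the named-gene rule, the design and the main alternatives were fixed before the data were examined. The 36 lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01, and adjusted over the lists. All 10 lists called in this way lost the call when the correlation was estimated, where the lowest camera adjusted p was 0.503. The estimate was above the preset in some of these lists, such as 0.238 for G2/M genes. In others it was below, such as -0.0492 for mesenchymal markers, so a higher correlation does not account for every lost call. The hypoxia list, with an estimate of -0.0278, went from an adjusted p of 3.8e-05 to 0.503 with camera. With an estimated correlation camera also rests on the few residual degrees of freedom of 4 libraries. Few lists could pass there, so the lost calls do not show how much correlation between genes weakens a list. All 10 were also called in the same direction by fry. That test asks whether the genes of a set move one way and does not compare them with other genes. Named genes were KDM1A, PXN and LPAR6, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, and up to 4 called members per list with the smallest adjusted p. Other genes are marked as named after their values were seen, and some genes that the rule names are not reported here.

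Alternatives were DESeq2 size factors, no normalization factor, no filter, a filter of 1 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, sums over the rows of a symbol and leaving out each library. Other splits of the samples were not counted, as each group has 2 libraries. Keeping the unmatched rows and leaving out genes with a candidate 7-mer for either duplex were added after the data were seen. The candidates were TACTTCG, ACTTCGA, GCGTACA, CGCGTAC, CTAGAAG and TAGAAGA, chosen after the fold changes were seen. Neither duplex sequence is known, so a match to the duplexes used is not established. On simulated counts for this comparison, over 13143 genes, the test recovered 73.1% of 67 genes changed 1.5-fold. It recovered 92.5% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 6.35% false calls among 189. The changed genes had at least 1 CPM, and the spread was taken from these data. Changes under 1.5-fold were not planted, so these rates do not describe smaller changes, which include many of the calls. In a separate simulation both of 2 moved lists were called and 0 others. Its counts were drawn independently for each gene, so it cannot show how often correlated genes give false list calls. Sequence searches used the GENCODE transcripts of 10185 genes with a mean of at least 5 CPM, run in Python 3.11.15 with scipy 1.17.1.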

Results

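RNA was sequenced from PC-3M-luc cells, a metastatic, androgen-independent human prostate carcinoma line that carries a luciferase reporter. Cells received either a control RNAi duplex or a duplex against LSD1 and were harvested 72 h after transfection. LSD1, encoded by KDM1A, is a flavin-dependent demethylase that removes methyl groups from histone H3. Each group held 2 libraries, which the labels call biological replicates. The p-values rest on a spread between replicates that is shared across genes. Counts assigned to genes were 12474183 and 12410719 in the control libraries and 12040681 and 12831374 in the knockdown libraries. At these depths, 3 counts in a library corresponded to 0.234 to 0.249 CPM (counts scaled to library size). Replicates of a group differed by more than counting noise, with a chi-square per gene of 5.001 between the control libraries and 4.30 between the knockdown libraries, against 26.7 to 29.2 between libraries of different groups.

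The comparison of knockdown with control cells addresses which transcripts change when LSD1 is depleted in this line. KDM1A itself (NM_001009999) fell from 236.6 ± 2.09 CPM (SD, n = 2) to 17.97 ± 0.169 CPM (SD, n = 2), or 7.60% of control, with raw counts of 2920 and 2892 in control libraries and 218 and 234 in knockdown libraries. The log2 fold change was -3.72 with a standard error of 0.0974 (edgeR quasi-likelihood test, adjusted p = 2.32e-24). Of 13247 genes tested, 2413 rose and 2375 fell at an adjusted p under 0.05, together 36.1% of the genes. Most changes were small, since the median absolute log2 fold change of the called genes was 0.475, and 292 genes rose and 221 fell by at least 2-fold. The median log2 fold change over all tested genes was 0.0024. Values of the 2 groups did not overlap for 8897 genes, or 67.2%, where chance gives 33.3%. DESeq2 called fewer genes, 1564 higher and 1618 lower.

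PXN, which encodes the focal adhesion scaffold paxillin, and LPAR6, which encodes a receptor for lysophosphatidic acid, were singled out in advance, and both rose after LSD1 knockdown. PXN (NM_001243756) went from 365.9 ± 23.5 to 927.3 ± 59.4 CPM (SD, n = 2 each), a 2.53-fold rise with a log2 fold change of 1.34 and a standard error of 0.0857 (edgeR adjusted p = 9.1e-14). LPAR6 rose 1.53-fold, from 16.86 ± 1.30 to 25.85 ± 2.23 CPM (SD, n = 2 each), with a log2 fold change of 0.62 and a standard error of 0.12 (edgeR adjusted p = 0.000151). The exons of PXN overlap those of the antisense gene PXN-AS1 over 464 nucleotides, and counting is not stated to use strand. The PXN coding sequence also holds TACTTCG and ACTTCGA, which belong to a set of 7-mers whose holders were more often higher in the knockdown libraries. LPAR6 holds none of that set.

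**Figure D1:**
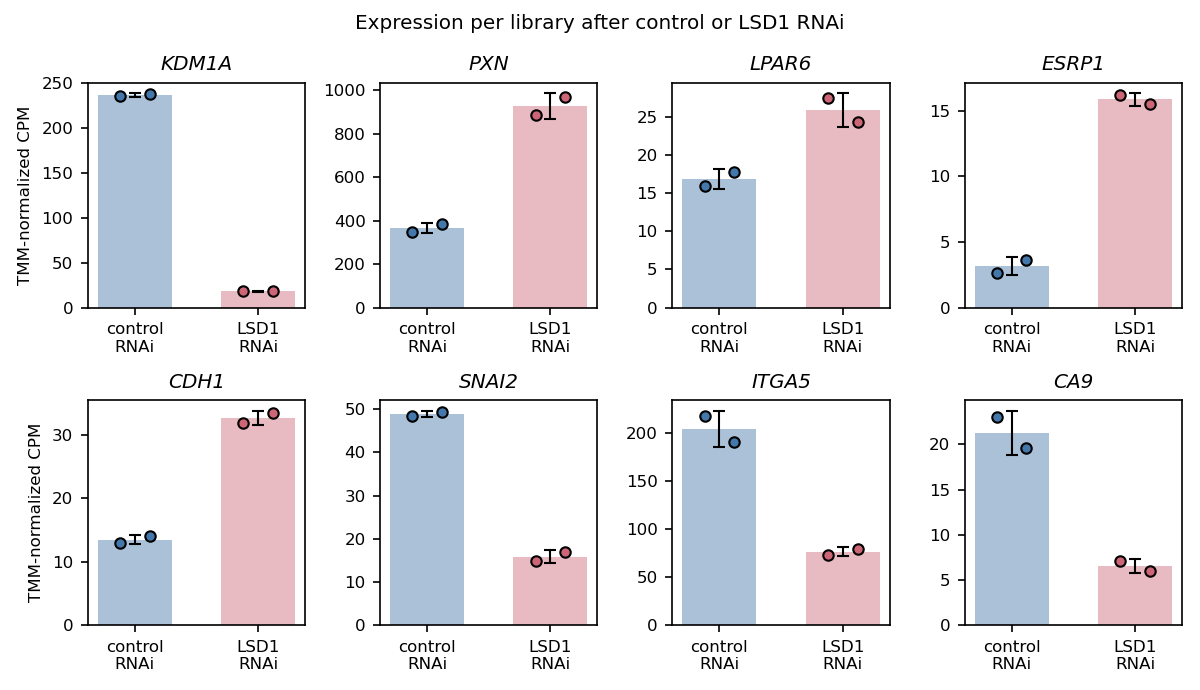
TMM-normalized CPM of 8 genes in PC-3M-luc cells after control RNAi or LSD1 RNAi. Points are libraries, bars are means of 2 libraries and error bars are SD; KDM1A fell to 7.60% of control while PXN rose 2.53-fold.

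Other focal adhesion genes went both ways. Of 33 tested, 7 rose, 13 fell and 13 did not pass (8 and 14 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.211). PARVB, a parvin of the integrin-linked kinase complex, rose by a log2 fold change of 0.80 and TLN1, the talin that links integrins to actin, by 0.63. FLNA, an actin crosslinking filamin, fell from 2942 to 1526 CPM. Among 13 integrin subunits 2 rose and 4 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.211). ITGA5, a subunit of the fibronectin receptor, fell 2.67-fold, ITGA2 fell 1.58-fold and ITGB5 fell 1.42-fold, while ITGB8 rose 1.41-fold. In the lysophosphatidic acid list 6 of 14 genes rose and 1 fell, S1PR1, chosen after its values were seen, with the same counts adjusted over the list alone (camera adjusted p = 0.0875). ARHGEF11 and GNA12 rose 1.65-fold and 1.55-fold, and the sphingosine phosphate receptor gene S1PR2 rose 1.85-fold.

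Among called genes with a mean of at least 5 CPM and no overlap between the groups, the largest rise was that of MMP13, a collagenase, from 4.86 ± 1.63 to 34.75 ± 1.81 CPM (SD, n = 2 each), a log2 fold change of 2.84. SLC35F5, a predicted solute carrier, followed at 2.41, then ESRP1, an epithelial splicing regulator, at 2.34 and SPINK5, a serine protease inhibitor, at 2.25. KMO, an enzyme of tryptophan breakdown, rose by 1.99, SPARC, a secreted matrix protein, by 1.97, CSRNP3 by 1.89, FAM20A by 1.88, ARMC9 by 1.79 and ARL6IP1 by 1.76. After KDM1A, the largest falls were those of C18orf32 at -2.33, HMOX1, which degrades heme, at -2.10 and B4GALNT1, a ganglioside synthesis enzyme, at -2.07. KIAA0319, RWDD1, NXPE3, the protocadherin gene PCDH7, the Notch ligand gene DNER and the carbonic anhydrase gene CA9 fell by log2 fold changes between -1.92 and -1.71. The edgeR adjusted p of these 20 genes was 8.05e-09 or lower. C18orf32 is uncertain because its exons lie over 918 nucleotides of the readthrough gene RPL17-C18orf32, and KMO overlaps OPN3 on the opposite strand over 1568 nucleotides. Values of RBBP4, which overlaps SYNC over 1706 nucleotides, and of FEN1, CDKN2A, MMP1, NDUFS1, PARP9, PGK1, RPL35, SDHC, SLC7A11, TLN1, TNFRSF10B and VLDLR, which also overlap other genes, are uncertain to unequal degrees. The overlapping gene can be rare, as WTAPP1 with a mean count of 3.5 beside 398.8 for MMP1. It can also be abundant, as DTX3L with 1159.8 beside 664.5 for PARP9. SLC35F5 and SPARC hold a 7-mer of the set found in PXN, as do PCDH7 and DNER among the genes that fell, while RWDD1, NXPE3 and KDM1A share the 8-mer CTAGAAGA.

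**Figure D2:**
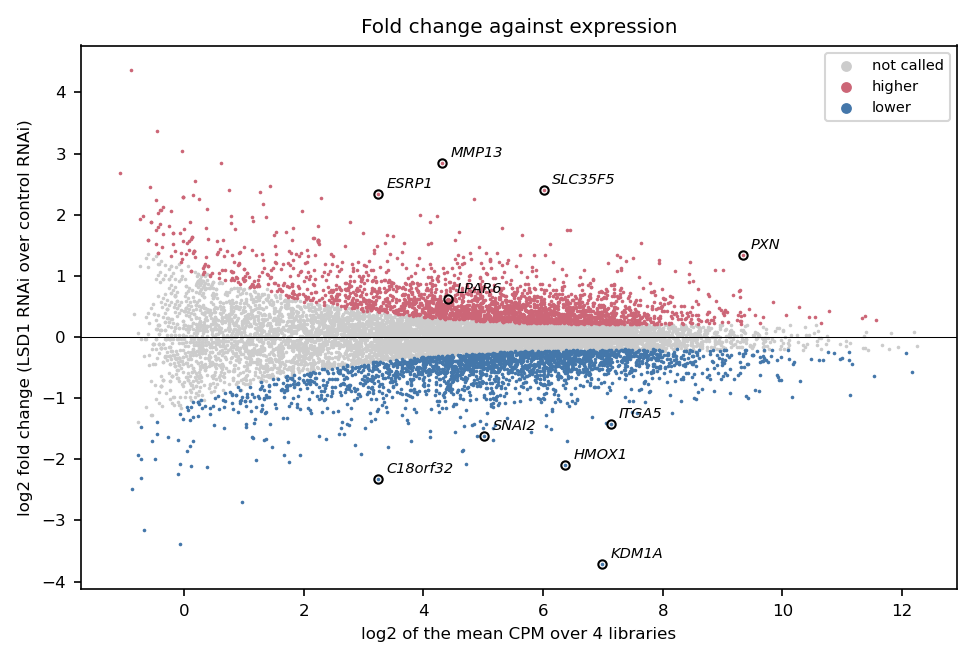
Log2 fold change of LSD1 RNAi over control RNAi against the log2 of the mean CPM, one point per tested gene, with genes at an edgeR adjusted p under 0.05 colored as higher or lower. KDM1A lies lowest at -3.72, and among the circled genes MMP13 lies highest at 2.84.

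Most of the cell division genes tested fell. Of 40 G2/M genes 34 fell, 0 rose and 6 did not pass (35 fell adjusted over the list alone), with a median log2 fold change of -0.48 (camera adjusted p = 1.12e-11, adjusted p = 0.519 with an estimated correlation). ANLN, which organizes the cytokinetic ring, fell 2.12-fold, HMMR, a spindle protein, 2.06-fold, UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, 2.00-fold and TPX2, a spindle assembly factor, 1.68-fold. Of 40 G1/S genes 30 fell, 1 rose and 9 did not pass (31 and 1 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 7.26e-09, adjusted p = 0.503 with an estimated correlation). The ribonucleotide reductase genes RRM1 and RRM2 fell 1.76-fold and 1.67-fold, the flap endonuclease gene FEN1 1.78-fold and the replicative helicase gene MCM5 1.73-fold. CCNE1, a cyclin of G1/S entry named after its values were seen, rose by 1.17. Among 21 cell cycle inhibitors, D cyclins and RB family genes 2 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.342). E2F5, a repressive E2F, rose 2.995-fold, while E2F7 fell 1.91-fold, CDKN2A 1.40-fold and CCND3 1.44-fold. The 22 p53 targets, in a line derived from cells without functional p53, held 3 that rose and 5 that fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.873), with a median of 0.03 against a mean of -0.05 and a downward test direction. GADD45A fell 1.75-fold and TNFRSF10B rose 1.31-fold.

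More epithelial adhesion genes rose than fell, and more mesenchymal genes fell than rose. In the epithelial list 10 of 26 genes rose, 3 fell and 13 did not pass (14 and 3 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.0154, adjusted p = 0.536 with an estimated correlation). ESRP1 rose from 3.14 ± 0.682 to 15.87 ± 0.477 CPM (SD, n = 2 each), CDH1, which encodes E-cadherin, rose 2.42-fold and CDH3, which encodes P-cadherin, 1.66-fold. The genes that fell were the plakophilin gene PKP1, down 1.603-fold, and, named after their values were seen, CLDN4 and DSC2. In the mesenchymal list 8 of 20 genes fell, 2 rose and 10 did not pass, with the same counts adjusted over the list alone and a median of -0.29 (camera adjusted p = 0.0241, adjusted p = 0.503 with an estimated correlation). SNAI2, a transcriptional repressor of E-cadherin, fell 3.08-fold, NT5E, a cell surface nucleotidase, 2.74-fold and CDH11, a mesenchymal cadherin, 1.94-fold. SPARC rose, as did SNAI1, another E-cadherin repressor named after its values were seen, by 0.57. The mesenchymal call was lost, at a camera adjusted p of 0.0519, when genes holding a candidate 7-mer for either duplex were left out. The mesenchymal median then went from -0.29 to -0.49.

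Matrix proteases and matrix proteins held large changes in both directions. Among 26 proteases and inhibitors 5 rose and 12 fell (6 and 12 adjusted over the list alone, camera adjusted p = 0.143). Besides MMP13, the interstitial collagenase gene MMP1 rose 2.20-fold, whereas the protease inhibitor gene SERPINE2 fell 2.01-fold and CTSL, a lysosomal protease gene, 2.20-fold. Among 30 matrix genes 5 rose and 13 fell (5 and 15 adjusted over the list alone, camera adjusted p = 0.0967). COL5A2, a fibrillar collagen gene that holds TACTTCG and ACTTCGA in its 3′ UTR, rose 2.44-fold, whereas the fibrillin gene FBN1 fell 2.93-fold and the tenascin gene TNC 2.37-fold.

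In the hypoxia, glycolysis and immediate early lists more genes fell than rose. Of 27 hypoxia and angiogenesis genes 17 fell, 1 rose and 9 did not pass (18 and 1 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 3.8e-05, adjusted p = 0.503 with an estimated correlation). CA9, which regulates pH, fell from 21.31 ± 2.43 to 6.54 ± 0.828 CPM (SD, n = 2 each), ANGPTL4, a secreted lipase inhibitor, fell 2.91-fold, BNIP3, a mitophagy receptor, 2.83-fold and NDRG1 1.98-fold. The gene that rose was HIF1A, the hypoxia-inducible factor subunit, by 0.28, named after its values were seen. Of 20 glycolysis genes 12 fell, 1 rose and 7 did not pass (15 and 1 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.00077, adjusted p = 0.503 with an estimated correlation). ENO2 fell 3.22-fold, PFKP 1.65-fold, PGK1 1.66-fold and the glucose transporter gene SLC2A1 1.59-fold, while PFKM, named after its values were seen, rose by 0.64. The hypoxia and glycolysis lists share members such as SLC2A1. Among 22 AP-1 and immediate early genes 11 fell and 2 rose, also adjusted over the list alone, with a median of -0.31 (camera adjusted p = 0.00228, adjusted p = 0.536 with an estimated correlation). JUN, an AP-1 subunit, fell 2.35-fold, KLF6, a zinc finger factor, 2.30-fold, FOSL1 1.53-fold and PHLDA1 1.53-fold, while FOS and SPRY4, named after their values were seen, rose by 0.75 and 0.36.

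Stress genes divided. In the amino acid and unfolded protein list 14 of 28 genes fell and 2 rose, also adjusted over the list alone, with a median of -0.24 (camera adjusted p = 0.0196, adjusted p = 0.503 with an estimated correlation). PSPH, the last enzyme of serine synthesis, fell 2.58-fold and VLDLR 2.11-fold, while the cystine transporter gene SLC7A11 rose 2.31-fold and EDEM1, a factor of endoplasmic reticulum degradation, 2.32-fold. This call was lost without control replicate 1, where the median was -0.20. It was also lost without genes holding a candidate 7-mer for either duplex, at a camera adjusted p of 0.0774 and a median of -0.15. Of 20 oxidative stress genes 4 rose and 8 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.292). Besides HMOX1, GCLM, a subunit of the glutathione synthesis enzyme, fell 2.74-fold and the thioredoxin gene TXN 1.86-fold.

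In the cholesterol synthesis and interferon lists more genes rose than fell. Of 24 cholesterol genes 13 rose, 1 fell and 10 did not pass (15 and 1 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.00191, adjusted p = 0.503 with an estimated correlation). DHCR7, the last enzyme of the pathway, rose 1.74-fold, the demethylase gene CYP51A1 1.75-fold and INSIG1, which holds back sterol synthesis, 1.66-fold. The gene that fell was MSMO1, by 0.32 on the log2 scale, named after its values were seen. Of 31 interferon genes 12 rose, 3 fell and 16 did not pass, with the same counts adjusted over the list alone and a median of 0.29 (camera adjusted p = 0.0106, adjusted p = 0.503 with an estimated correlation). IFIT2, which binds RNA, rose 2.30-fold, IFITM2, which restricts viral entry, 1.67-fold and PARP9 1.55-fold. ISG20, an exonuclease, fell 2.65-fold, and IFI6 and SAMD9, named after their values were seen, also fell. Respiratory chain genes held 13 that rose and 2 that fell of 37 (14 and 3 adjusted over the list alone, camera adjusted p = 0.137). UQCRC2 rose 1.44-fold, NDUFS1 1.46-fold and COX6A1 2.03-fold, whereas SDHC fell 2.08-fold. The COX6A1 value rests on knockdown replicate 1, at 642.4 CPM against 290.7 CPM in knockdown replicate 2, and DESeq2 did not call it (DESeq2 adjusted p = 0.197).

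**Figure D3:**
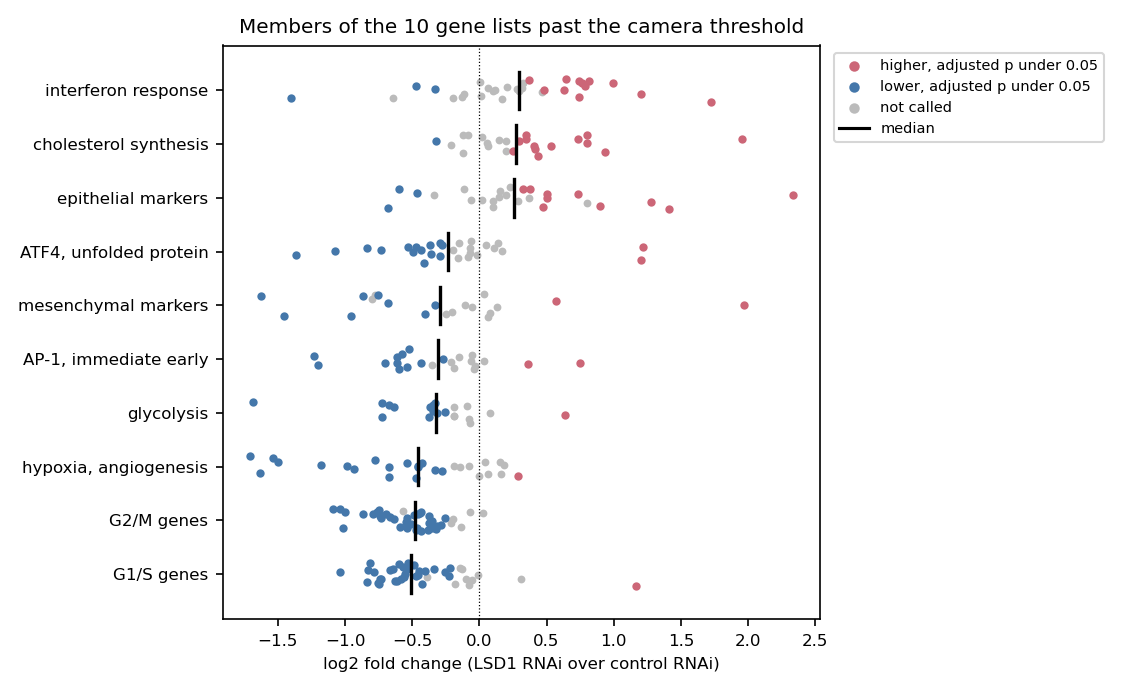
Log2 fold change of each tested member of the 10 gene lists past the camera threshold, one row per list, with members at an edgeR adjusted p under 0.05 colored and medians as black lines. The medians run from -0.51 in the G1/S genes to 0.29 in the interferon genes.

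LSD1 partner genes and the other lysine demethylases were not called as lists. Among 25 genes of LSD1 complexes 6 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.522), and the median of 0.09 and the test pointed up while the mean of -0.02, which includes KDM1A, pointed down. ZMYM3 rose 1.32-fold and the histone-binding gene RBBP4 fell 1.27-fold. Of 18 other demethylases 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.391), with KDM5B up 1.48-fold, KDM7A up 1.61-fold and KDM3A down 1.46-fold.

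Among 16 genes often used as references 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.731), with PGK1 down 1.66-fold and IPO8 up 1.39-fold. Of 40 ribosomal protein genes 0 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.211), and RPL35 fell 1.29-fold. Among 16 replication-dependent histone genes, whose mRNAs mostly lack poly(A) tails, 5 rose and 3 fell (camera adjusted p = 0.351). Of 5 structural RNAs 1, SCARNA2, rose (camera adjusted p = 0.973). Both sets of counts were the same adjusted over the list alone. Markers of other cell types gave no list call. Of 3 leukocyte markers tested, too few for a list test, CD68, a lysosomal protein of macrophages and other cells, fell 1.89-fold, CD79A fell 2.02-fold, and LYZ rose from 4 and 2 counts to 17 and 13, so that their median of -0.92 and mean of 0.10 differ in sign. Of 6 fibroblast and endothelial markers KDR and COL1A2 rose 2.25-fold and 1.52-fold and PECAM1 fell 1.67-fold (camera adjusted p = 0.731), with a median of -0.18 and a mean of -0.01. No erythroid or liver marker passed the filter on low counts, and the highest count in any library was 13. The calls of CD79A, LYZ, COL1A2, PECAM1 and SCARNA2 were each lost in at least 1 other setting, such as leaving out a library.

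Genes whose annotated 3′ UTR or coding sequence holds TACTTCG, ACTTCGA, GCGTACA or CGCGTAC were called higher in 34.2% of cases against 17.2% of other genes, with the 7-mers picked after the fold changes were seen. Among searched genes, which have a mean of at least 5 CPM, 118 were higher by at least 2-fold and 46.6% of these held such a 7-mer, against 15.5% of other genes, and of 119 lower by at least 2-fold 9.2% did, against 15.9% of others. Other genes named here that hold 1 or more of these 7-mers include TGFBR1, SLC7A11, KDM5B, KDM7A, ZMYM3, CDH3, IFITM2, UQCRC2 and IPO8, which rose, and FLNA, RRM1, NDRG1, SLC2A1 and SDHC, which fell. The 8-mer CTAGAAGA is also held by RBBP4, ANLN, HMMR, CDKN2A, PKP1, CDH11 and PSPH, which fell, and by TNFRSF10B, KDM5B, KDR and COL1A2, which rose.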

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

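A signal appeared in rows left out of the comparison. Of 511 unmatched rows that passed the count filter, 65 were higher and 66 were lower in the knockdown libraries at an edgeR adjusted p under 0.05, in a fit chosen after the data were seen. These rows have no gene symbol here and were not followed further.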

How the results depend on the processing

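KDM1A kept its direction and call in every alternative run that tested it, with log2 fold changes from -3.729 to -3.683. The range was -3.729 to -3.710 when each library was left out in turn. KDM1A holds CTAGAAGA, so it was absent from the run without genes holding a candidate 7-mer. Genes higher numbered 2413 in the main test and 1564 with DESeq2, against 2375 and 1618 lower; DESeq2 kept 3179 of the 4788 calls and gave no adjusted p for 771 genes, and the cause was not tested. Leaving out 1 library, with the lone remaining library assumed to vary like the other group, gave 1772 to 1988 genes higher, 1889 to 1998 lower and 9 to 11 gene lists. No called gene changed sign, except 3 without control replicate 2. With no normalization factor 2758 genes were higher and 2091 lower. Leaving out genes with a candidate 7-mer for either duplex, chosen after the data were seen, gave 1319 genes higher and 1308 lower, since fewer genes are tested. Of the 2695 calls still present, 2593 were kept. The 10 list calls became 0 with an estimated correlation and 18 with fry, whose question differs. In the labels, replicates of equal number share only that number. The correlation of their deviations across 13247 genes was 0.0676, which does not exclude a shared batch. The fit with the replicate block gave 2629 genes higher, 2630 lower and 10 lists. Of 148 named genes other than KDM1A, 127 kept their call under every setting fixed in advance and 21 lost it in at least 1, none with a change of sign. Those 21 include HLA-G, COX6A1, PECAM1, LYZ, CD79A, COL1A2 and SCARNA2. Low depth limits genes such as LYZ, at 2 to 17 counts.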

Other observations

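Groups not described so far also held large changes, without a list call. Of 15 neuronal genes repressed by REST and CoREST 6 rose and 5 fell (camera adjusted p = 0.973), with a median of 0.0007 against a mean of -0.01 and a downward test; ENO2 fell 3.22-fold, the neurofilament gene NEFL 1.97-fold and the tubulin gene TUBB3 1.38-fold. Among 13 androgen receptor and luminal genes 5 rose and 3 fell (camera adjusted p = 0.556), with SLC45A3, a prostate membrane transporter, up 1.82-fold and STEAP1, a metalloreductase family member, down 1.61-fold. The 22 TGF-beta genes held 5 that rose and 8 that fell (camera adjusted p = 0.973), with a median of 0.06 and an upward test against a mean of -0.04; the receptor gene TGFBR1 rose 2.86-fold, while ID1, an inhibitor of DNA binding, fell 2.51-fold. YAP and TEAD targets split evenly, 5 up and 5 down of 22 (camera adjusted p = 0.731). Of 12 Wnt genes 3 rose and 4 fell (camera adjusted p = 0.211), with LGR5, a stem cell receptor, up 3.44-fold and WNT7B down 2.38-fold. All of these counts were the same adjusted over the list alone.

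Inflammatory genes numbered 2 up and 2 down of 17 (camera adjusted p = 0.731), with a median of 0.02 against a mean of -0.15 and a downward test; CSF1, a macrophage growth factor, fell 2.92-fold and the adhesion receptor gene ICAM1 rose 1.62-fold. Antigen presentation genes numbered 4 up and 2 down of 15 (camera adjusted p = 0.292), with the peptidase gene ERAP2 up 1.74-fold; HLA-G shares sequence with its paralogs and is uncertain. Fatty acid genes numbered 8 up and 4 down of 24 (camera adjusted p = 0.351), with the desaturase gene SCD up 1.49-fold and the nuclear receptor gene PPARD down 2.09-fold. Apoptosis regulators numbered 4 up and 5 down of 22 (camera adjusted p = 0.636), with the survival gene BCL2L1 down 1.52-fold, and autophagy and lysosome genes 2 up and 8 down of 26 (camera adjusted p = 0.213), with the protease gene CTSD down 1.43-fold. These counts, too, were the same adjusted over the list alone.

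In what follows, the tests of GL3 and of shuffled genes were fixed before their results were seen, and the other tests were chosen after. The 7-mers were ranked by the z of their holders' fold changes after regression on 3′ UTR length, GC content and expression. The highest in 3′ UTRs of 10104 genes were GCGTACA (z = 7.73, 111 genes, unadjusted mean log2 fold change 0.31), TACTTCG (z = 7.60, 150 genes, 0.25) and ACTTCGA (z = 7.0, 178 genes, 0.22). Chance among many 7-mers is argued against by the highest z of 4.95 over 100 shuffles. After the regression, holders of these 7-mers differed from other genes by a mean of 0.23 (SE 0.022). The 7-mers were picked on the same adjusted values, so this difference is no separate test of 3′ UTR length and GC content. These 7-mers match seeds of a luciferase duplex known as GL2, whose sequence was taken from general knowledge, and a control duplex with this sequence that lowered such genes in the control libraries stays open as a candidate explanation. All 4 seed 7-mers of its strands rank among the 20 highest, but the duplex was picked from these ranks, so they cannot decide it. The related GL3 duplex shares TACTTCG and ACTTCGA with GL2 through its antisense strand. The 7-mers of the GL3 sense strand, AGCGTAA and GCGTAAA, reach a z of -1.14 and -0.17 in 3′ UTRs. That argues against an effect of the GL3 sense strand, but cannot decide on GL3, whose antisense strand has the same seed 7-mers as GL2. The lowest 7-mer was CTAGAAG (z = -5.31, lowest shuffled -5.08), and the KDM1A coding sequence holds CTAGAAGA, as do those of 5.43% of genes, so the LSD1 duplex may have such a seed; neither duplex sequence is given in the sources used here.

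For PXN, a direct effect of the control duplex cannot be told apart from an effect of LSD1, because every control library received the control duplex and every knockdown library another. PXN holds TACTTCGA in the coding sequence, and its change lies at percentile 98.6 among 142 genes that hold it, with 1 gene above. The mean log2 fold change of these genes was 0.256. A fit required a change between -0.655 and 1.158, bounds that leave out the extremes of these genes. PXN, at 1.34, lay above them, so this criterion was not met, and the question stayed undecided because PXN holds the 7-mers. Of the 118 searched genes higher by at least 2-fold 46.6% hold a 7-mer of the set, and of the 119 lower by at least 2-fold 9.2% do. The 7-mers were picked from the same fold changes, so these shares cannot decide the question for PXN. LPAR6 holds 0 of the GL2 seed 7-mers in its coding sequence and 3′ UTR, which argues against direct repression of LPAR6 through these 7-mers. The control duplex sequence is unknown, so repression through another sequence, a loss of LSD1 and indirect effects stay open.

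Without genes holding a candidate 7-mer for either duplex, 8 of the 10 lists keep call and direction. The calls of these 8 lists therefore do not rest on genes holding these 7-mers alone. The bound of 8 was itself set after this count was seen. It cannot decide whether direct matches to these 7-mers cause the gene list changes. Seeds other than the candidates are not covered, since neither duplex sequence is known. The mesenchymal list, with a median of -0.29 before and -0.49 after, and the amino acid and unfolded protein list, with -0.24 before and -0.15 after, lost their calls with fewer members tested. Effects of either duplex through other genes, and an effect of LSD1 loss, may both contribute and were not separated.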
